A study of Homo sapiens with 12 samples.

How the data were processed

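Expression was measured in 12 samples of LNCaP MYC cells on Illumina BeadChips, 3 for each combination of treatment (2 ug/mL doxycycline or ethanol vehicle) and time (5 h or 12 h). The non-normalized table deposited with the series holds, for each of 47323 probes, an intensity per array on a linear scale, from 65.4 to 15272, without background subtraction. Beside each intensity, the deposited table gives a detection p-value, in steps that imply 770 negative control beads. The submitters' notes name GenomeStudio 2011.1 as the software, and bead summary settings were not stated. The series matrix holds intensity values that the authors quantile normalized on the linear scale, with a median of 95.8 on every array. Ranks within an array equalled those of the non-normalized values. Mean intensity per array lay between 212 and 284, and replicates of a group correlated at 0.985 to 0.994 across probes, with no duplicated arrays.

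Values were computed from the non-normalized table in R 4.3.3 with limma 3.58.1. Background was corrected with neqc, which models it from the detection p-values, followed by an offset of 16, quantile normalization and log2. Probes with a detection p under 0.05 on at least 3 of the 12 arrays were kept, 20454 in all. Of these, 14906 carried a single gene symbol and gave 11364 genes, with the probe of highest mean standing for a gene where several were detected (2778 genes). Symbols were looked up by Entrez identifier for 30074 probes and none changed. The remaining 5548 kept probes, unnamed or with several symbols, were left out of the gene tests and tested apart. Of the called genes named by the rule below, 11 at 12 h and 1 at 5 h had other detected probes (14 and 1), of which 0 had the opposite sign. Sizes could differ. At 12 h the other SLC6A9 probe was at 0.016 against 0.73, and that of DHX37 at 0.40 against 0.95. Other probes of DPH2 were at 1.12 and 0.96 against 1.04. At 5 h the other PFKFB3 probe was at 0.33 against 0.75.

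A limma model of 4 group means was fitted to all 12 arrays (8 residual degrees of freedom), with moderated two-sided tests. The comparisons were Dox against vehicle at 5 h and at 12 h, the difference between these effects, and vehicle at 12 h against 5 h. P-values were adjusted by Benjamini-Hochberg within each comparison and called at an adjusted p under 0.05. The test of overlap was a one-sided Fisher's exact test. Gene lists were compiled from general knowledge, 27 lists with 775 memberships, of which 724 had a named probe; genes without a named probe were not analysed here. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the 27 lists, and again with the correlation estimated from the data. The second form was stricter even where that estimate lay near 0. At 12 h the ATF4 and endoplasmic reticulum stress list had an estimate of -0.0017, yet its unadjusted camera p went from 2.8e-11 to 7.9e-05. A call lost in the second form therefore need not reflect correlation between genes. Where a gene was detected on no array of a group, its fold is a bound computed from the detection floor.

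Same-numbered Dox and vehicle arrays of a time deviated from their group means together, with r from 0.17 to 0.549 in 6 pairs, and 11 of 12 arrays matched best with their own number. Same-numbered arrays of different times gave r from -0.294 to 0.103 in 12 pairs. Differently numbered Dox and vehicle arrays of a time gave r from -0.502 to 0.201 in 12 pairs, a range that overlaps that of the same-numbered ones. A paired fit with the number as a block within each time (4 residual degrees of freedom) was therefore run beside the fit without it. This fit was chosen after the data were examined.

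The comparisons, tests, lists, filters, other settings to be tried and the rule for naming genes were fixed before the data were examined. The rule named MYC, the 12 largest rises and 12 largest falls per Dox comparison among called genes whose groups did not overlap, all measured genes of de novo purine synthesis and the MYC network, and in every other list up to 4 called members, or 2 where none was called. The settings tried were no background correction, median scaling, cyclic loess, the authors' normalized values, an offset of 50, no detection filter, a stricter filter (p under 0.01 on all 12 arrays) and the replicate number as a block across times. Others were only the compared groups in the fit, array quality weights, an intensity trend with a robust prior, all probes, the mean of a gene's probes, limma's treat against a 1.5-fold change, each array left out in turn, and for lists the estimated correlation and fry, a rotation test.

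The procedure was tested on simulated data with 200 of 11364 genes changed. At 1.5-fold, 2-fold and 3-fold it recovered 58.2%, 92.5% and 98.5% of changed genes for Dox against vehicle at 5 h, and 49.3%, 92.5% and 98.5% at 12 h. For the difference of the effects it recovered 14.9%, 53.7% and 83.3%, and for the vehicle times 40.3%, 86.6% and 98.5%. Of 11147 unchanged genes, 7, 5, 3 and 9 were called in these comparisons, and 0 genes were called with no change simulated. A list shifted by 0.30 was recovered in each comparison, with 0 other lists called. Genes were drawn independently of each other, whereas the estimated correlation of the real lists reached 0.42 (G1/S and DNA replication). The simulation thus leaves open how often camera calls unshifted lists of correlated genes. Pairs of arrays, background correction and normalization were not simulated.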

Results

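LNCaP, an androgen-responsive human prostate cancer cell line, was studied here in a derivative labelled LNCaP MYC, known to carry a MYC transgene that doxycycline switches on. Cells had been held in hormone-depleted serum for 72 h and then received doxycycline at 2 ug/mL or the ethanol vehicle. RNA was taken after 5 h and after 12 h and read on expression BeadChips, giving 12 arrays in 4 groups of 3. The title of the series places the question in the control of purine synthesis by MYC and in the expression of oncogenes and tumour suppressors. Between 17427 and 18826 of the 47323 probes were detected on an array, and 11364 genes could be tested. The number of arrays limits the precision of every value below. The submitters call the samples of a group biological replicates, but whether they came from separate cultures was not given. P-values therefore measure only the spread between these samples, which may be technical. Unless stated otherwise, changes are log2 differences of arrays labelled Dox minus vehicle arrays of the same time, with the standard error of the limma fit (n = 3 arrays per group) and Benjamini-Hochberg adjusted p-values. A paired fit took same-numbered arrays of a time as pairs, and its value is given for some, not all, of the calls it changed.

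MYC, a transcription factor that drives growth and ribosome production, was read by a bright and a dim probe. The bright probe (ILMN_1680618) gave 10.42 ± 0.17 (SD, n = 3) in the arrays labelled Dox and 10.62 ± 0.088 in vehicle at 5 h, a difference of -0.21 ± 0.12 (limma adjusted p = 0.816). At 12 h it gave 10.33 ± 0.049 and 10.76 ± 0.12, a difference of -0.43 ± 0.12 (limma adjusted p = 0.115; paired fit, 0.0411). All 3 arrays labelled Dox lay below all 3 vehicle arrays at 12 h. The dim probe (ILMN_2110908) was detected on 1 of 3 arrays labelled Dox and 2 of 3 vehicle arrays at 5 h, and on 2 of 3 of each at 12 h. It differed by -0.82 ± 0.43 at 5 h and -0.90 ± 0.43 at 12 h (limma adjusted p over all detected probes = 0.879 and 0.545). No other processing tried turned the sign of the bright probe. A higher MYC level in the arrays labelled Dox was thus not seen, and whether either probe lies within the sequence of the construct is not known, so the directions below rest on the treatment labels.

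At 12 h, the lists of ribosome biogenesis, amino acid transport, serine and folate metabolism and tRNA charging shifted upward in the arrays labelled Dox, and the list of androgen receptor targets shifted downward. Of 11364 genes, 103 rose and 13 fell. The largest rises were those of ECE2, an endothelin-converting enzyme (1.31 ± 0.14, 2.48-fold, adjusted p = 0.00114), and of the Wnt ligand gene WNT10B (1.23 ± 0.18, adjusted p = 0.0082). RRP12, a ribosome export factor, rose by 1.12 ± 0.14 (adjusted p = 0.0025). MTHFD1L, the mitochondrial enzyme that makes formate for purine synthesis, rose by 1.12 ± 0.13 (adjusted p = 0.002). The amino acid transporter genes SLC7A2 and SLC1A3 rose as well, SLC7A2 by 1.11 ± 0.16 (adjusted p = 0.009). SLC1A3 was at least 1.76-fold higher (adjusted p = 0.00114) and CHAC1, a glutathione-degrading enzyme, at least 1.83-fold higher (adjusted p = 0.0049). Neither was detected on any vehicle array at 12 h, so a bound is given for both. TRMT61A, which methylates tRNA, rose by 1.05 ± 0.16, DPH2, which makes diphthamide, by 1.04 ± 0.12, and POLR1G, a subunit of RNA polymerase I, by 0.99 ± 0.19. FERMT1, an integrin adaptor, rose by 1.02 ± 0.16, and DHX37, an RNA helicase of ribosome assembly, by 0.95 ± 0.14.

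Falls at 12 h were fewer, with a median of -0.67 against 0.68 for the rises. PCED1B changed by -0.87 ± 0.13 (adjusted p = 0.0099) and TMEM45B by -0.87 ± 0.14 (adjusted p = 0.0117). The long non-coding RNA LINC00161 changed by -0.78 ± 0.15, and CCNG2, a cyclin linked to cell cycle arrest, by -0.71 ± 0.13. ZC3H12A, a ribonuclease, changed by -0.70 ± 0.14, as did NDP, a secreted Wnt pathway ligand (-0.70 ± 0.13), which was detected on 1 of the 3 arrays labelled Dox. KLK4, a prostate kallikrein protease, changed by -0.67 ± 0.12 (adjusted p = 0.0208) and SLC45A3, a prostate membrane protein, by -0.56 ± 0.11 (adjusted p = 0.0263). HSPA1L, TP53INP2, IL1RN and RWDD2A changed by -0.60, -0.58, -0.58 and -0.58. At an unadjusted p under 0.05 there were 1301 genes, with 568.2 to be expected by chance, and in 20.1% of genes the groups did not overlap, against 10% by chance. The paired fit gave 262 rises and 111 falls, with all 103 and 13 calls kept. The total of both fell to 17 genes without Dox 12 h replicate 1, 17 without replicate 2 and 49 without replicate 3, and to 9, 77 and 14 without vehicle 12 h replicate 1, 2 or 3.

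**Figure D1:**
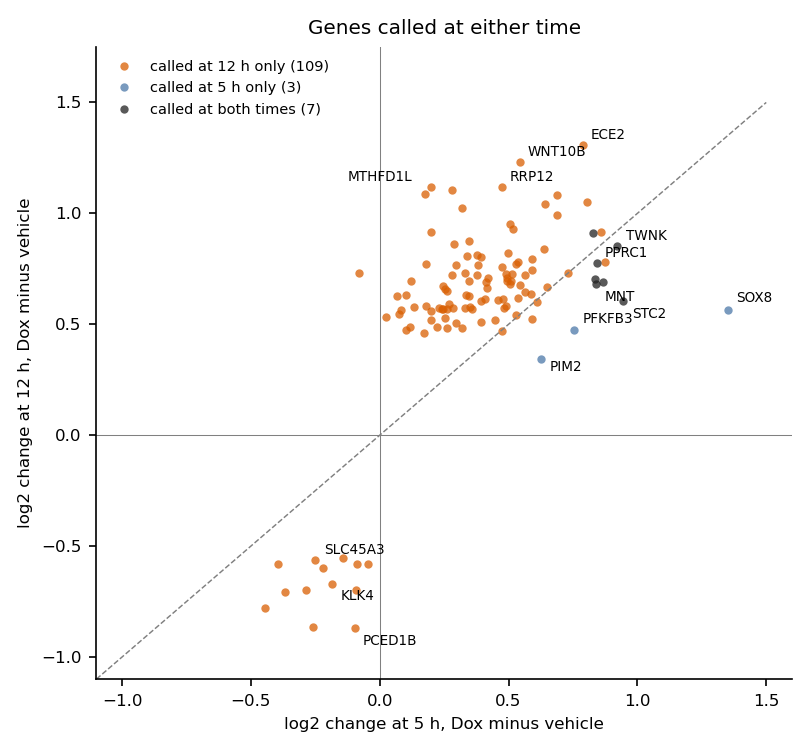
Log2 change at 5 h (horizontal axis) and at 12 h (vertical axis), arrays labelled Dox minus vehicle arrays, of the genes called at either time, with equal changes on the dashed line. Of the 103 genes that rose at 12 h, 102 lay above 0 at 5 h, and 7 were called at both times.

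The growth-related lists moved upward together at 12 h. Among 43 MYC target genes, 8 rose over all genes tested and 28 adjusted over the list alone (17 over all genes in the paired fit); 40 were higher, with a median of 0.40 (camera adjusted p = 4.3e-25; adjusted p = 0.0081 with an estimated correlation). Called members besides RRP12 included the small nucleolar RNA processing factor gene RRP9 (0.87 ± 0.14), the exosome subunit gene EXOSC5 (0.86 ± 0.10) and PUS1, a pseudouridine synthase (0.78 ± 0.16). Of 42 ribosome biogenesis genes, 10 rose (22 adjusted over the list alone) and 41 were higher, with a median of 0.37 (camera adjusted p = 2.2e-20; adjusted p = 0.0044 with an estimated correlation). Examples were NOL6 (0.82 ± 0.12), WDR36 (0.78 ± 0.12), BOP1 (0.76 ± 0.13) and the helicase gene DDX21 (0.70 ± 0.14), all nucleolar assembly factors. For mitochondrial biogenesis and import, 2 of 26 genes rose (2 adjusted over the list alone), the inner-membrane import genes TIMM10 (0.66 ± 0.12) and TIMM44 (0.57 ± 0.12). That list had a median of 0.19 (camera adjusted p = 7.1e-06; adjusted p = 0.0168 with an estimated correlation, 0.0718 when paired).

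Smaller shifts were found in 3 further lists of this kind, none of which held with an estimated correlation. Of 76 mitochondrial ribosomal protein genes, MRPS30 alone rose (0.49 ± 0.10; 1 adjusted over the list alone, 2 in the paired fit), and the median was 0.089 (camera adjusted p = 0.0019; adjusted p = 0.0515 with an estimated correlation). Of 30 translation factor genes, 0 passed limma's test (3 at an unadjusted p under 0.05, 0 adjusted over the list alone). Their median was 0.10 (camera adjusted p = 0.0038; adjusted p = 0.0869 with an estimated correlation), with EIF4EBP1, a translation inhibitor, at 0.74 ± 0.21. Among 27 genes of the RNA polymerase I and III machinery, a list that does not hold POLR1G, 0 passed limma's test (6 at an unadjusted p under 0.05, 4 adjusted over the list alone, 3 in the paired fit). Their median was 0.058 (camera adjusted p = 0.0061; adjusted p = 0.107 with an estimated correlation), with the polymerase subunit genes POLR1B at 0.59 ± 0.15 and POLR1C at 0.46 ± 0.12 (paired adjusted p = 0.037 and 0.0273). The other detected probe was at -0.12 for POLR1B and at 0.27 for POLR1C. Of 16 MYC network genes, MNT alone rose (0.68 ± 0.11, adjusted p = 0.0117), a repressor that shares the partner MAX with MYC. MXI1, another such repressor, was at 0.59 ± 0.15 (adjusted p = 0.0847, paired fit 0.0242), with its other detected probes at 0.39 and 0.13. Adjusted over the list alone, 2 genes were up and 1 was down, MYC itself. The list did not shift (camera adjusted p = 0.171).

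**Figure D2:**
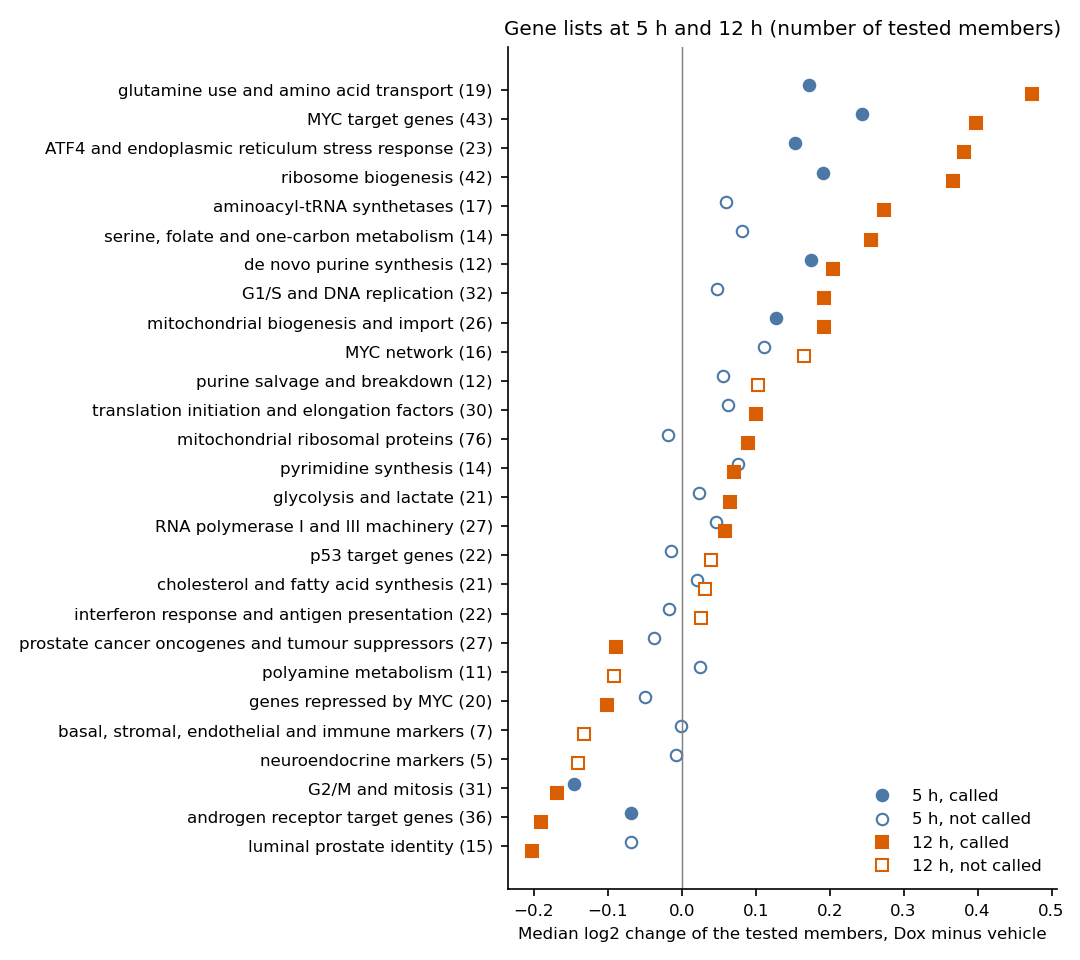
Median log2 change of the tested members of each of the 27 gene lists at 5 h (circles) and 12 h (squares), arrays labelled Dox minus vehicle arrays; filled symbols passed camera with its preset correlation. Glutamine use and amino acid transport stood highest at 12 h (0.47) and luminal prostate identity lowest (-0.20).

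The lists of amino acid transport, the ATF4 response, tRNA charging and serine metabolism shifted upward at 12 h. Of 19 genes of glutamine use and amino acid transport, 7 rose (12 adjusted over the list alone) and 17 were higher, with a median of 0.47 (camera adjusted p = 7.1e-12; adjusted p = 0.0017 with an estimated correlation). They included the glycine transporter gene SLC6A9 (0.73 ± 0.15), the cystine transporter gene SLC7A11 (0.66 ± 0.11), the cationic amino acid transporter gene SLC7A1 (0.60 ± 0.099) and ASNS, asparagine synthetase (0.57 ± 0.12). In the list of the ATF4 and endoplasmic reticulum stress response, 6 of 23 genes rose (10 adjusted over the list alone), with a median of 0.38 (camera adjusted p = 1.9e-10; adjusted p = 0.0017 with an estimated correlation). These included CHAC1, the pseudokinase gene TRIB3 (0.84 ± 0.12), the transcription factor gene CEBPB (0.77 ± 0.10) and STC2, a secreted glycoprotein (0.60 ± 0.12). Among 17 aminoacyl-tRNA synthetases, GARS1 (0.56 ± 0.12) and YARS1 (0.49 ± 0.10) rose, 7 adjusted over the list alone (4 over all genes when paired), and 16 were higher, with a median of 0.27 (camera adjusted p = 8.8e-08; adjusted p = 0.0024 with an estimated correlation). In serine and folate metabolism, 3 of 14 genes rose (7 adjusted over the list alone): MTHFD1L, PSPH (0.63 ± 0.12) and PSAT1 (0.58 ± 0.12), the last of which act in serine synthesis. That list had a median of 0.26 (camera adjusted p = 5.5e-06; adjusted p = 0.0143 with an estimated correlation). Of the 19 lists that passed camera at 12 h, 10 held with an estimated correlation, but 1 with median scaling and 5 with only the 2 groups in the fit.

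The 12 tested enzymes of de novo purine synthesis shifted upward as a group at 12 h, with 10 higher and a median of 0.20 (camera adjusted p = 0.00012; adjusted p = 0.0408 with an estimated correlation, 0.0385 when paired). None passed limma's test singly over all genes (0 of 12; 5 at an unadjusted p under 0.05), while 4 did adjusted over the list alone. The largest difference was that of PFAS, the formylglycinamidine synthase of the pathway (0.75 ± 0.22, adjusted p = 0.161; paired fit, 0.0144). PPAT, which catalyses the committed first step, followed (0.54 ± 0.13, adjusted p = 0.075; paired fit, 0.0211), and then the trifunctional enzyme gene GART (0.50 ± 0.12, adjusted p = 0.0709; paired fit, 0.0267). The other detected GART probes were at 0.26 and -0.020, so its change rests on the brightest probe. ADSL was at 0.35 ± 0.11, IMPDH1 at 0.26 ± 0.15, PAICS at 0.25 ± 0.10, IMPDH2 at 0.16 ± 0.13, ATIC at 0.14 ± 0.11 and GMPS at 0.13 ± 0.12. PRPS2 (0.055 ± 0.11), PRPS1 (-0.016 ± 0.14) and ADSS1 (-0.13 ± 0.16) lay near 0 within their errors. At 5 h, 9 of the 12 were higher with a median of 0.18 (camera adjusted p = 0.0134; adjusted p = 0.199 with an estimated correlation). There 0 passed limma's test (3 at an unadjusted p under 0.05, 0 adjusted over the list alone), with PFAS at 0.39 ± 0.22, PPAT at 0.38 ± 0.13, IMPDH1 at 0.36 ± 0.15 and GART at 0.33 ± 0.12. The other detected probes at 5 h were at 0.059 and -0.16 for GART and at 0.087 and 0.22 for IMPDH1. The 5 h shift was lost without vehicle 5 h replicate 1 (camera adjusted p = 0.0583), without Dox 5 h replicate 2 (0.0738) and with the mean of a gene's probes (0.108).

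**Figure D3:**
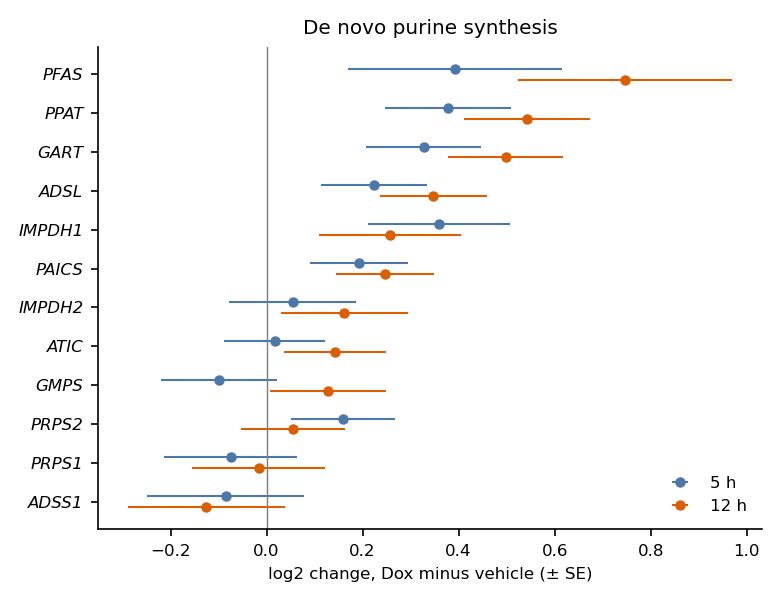
Log2 change (arrays labelled Dox minus vehicle arrays, bars ± SE, n = 3 arrays per group) of the 12 tested enzymes of de novo purine synthesis at 5 h and 12 h. PFAS, PPAT and GART, each by its probe of highest mean, stood highest at 12 h, and 10 of the 12 lay above 0.

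Among the other metabolic lists, pyrimidine synthesis and glycolysis passed camera at 12 h only with its preset correlation. Of 14 pyrimidine synthesis genes, 0 passed limma's test at 12 h (4 at an unadjusted p under 0.05, 2 adjusted over the list alone, 1 when paired), with CAD, which starts the pathway, at 0.65 ± 0.16 (paired adjusted p = 0.0446). The list's median was 0.070 (camera adjusted p = 0.0105; adjusted p = 0.317 with an estimated correlation). The call was lost without vehicle 12 h replicate 1 (0.0797) or 3 (0.0516). Of 21 glycolysis genes, 0 passed (4 at an unadjusted p under 0.05, 2 adjusted over the list alone, 2 when paired), with hexokinase gene HK2 at 0.64 ± 0.15 (paired adjusted p = 0.0386). Their median was 0.065 (camera adjusted p = 0.0323; adjusted p = 0.333 with an estimated correlation). That call was lost without vehicle 12 h replicate 1 (0.0779) or 3 (0.0807) and without Dox 12 h replicate 2 (0.0669) or 3 (0.135). The other detected HK2 probe was at 0.27. Purine salvage and breakdown (median 0.10, camera adjusted p = 0.171), polyamine metabolism (-0.091, 0.247) and cholesterol and fatty acid synthesis (0.032, 0.622) did not shift. Within them MTAP, which salvages adenine and methionine, rose by 0.61 ± 0.13 (adjusted p = 0.0458), and PNP, a purine salvage enzyme, was at 0.48 ± 0.15 (adjusted p = 0.179, paired fit 0.0312). In polyamine metabolism, which holds MTAP, 7 of 11 genes were lower, with 1 up and 2 down adjusted over the list alone. Purine salvage and breakdown passed camera without vehicle 12 h replicate 2.

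The lists of androgen receptor targets and luminal identity shifted downward at 12 h. Of 36 androgen receptor target genes, 2 fell, KLK4 and SLC45A3 (7 adjusted over the list alone, 5 over all genes when paired), and 27 were lower, with a median of -0.19 (camera adjusted p = 1.6e-06; adjusted p = 0.0024 with an estimated correlation). Of 15 luminal identity genes, 12 were lower, with a median of -0.20 (camera adjusted p = 0.0002; adjusted p = 0.0114 with an estimated correlation). Singly 0 of these passed limma's test (4 at an unadjusted p under 0.05, 2 adjusted over the list alone, 3 when paired). Among them ACP3, prostatic acid phosphatase, was at -0.89 ± 0.23 (adjusted p = 0.0981; paired fit, 0.0144), and the homeobox gene HOXB13 at -0.48 ± 0.12 (0.0784; paired fit, 0.0427).

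Of 27 prostate cancer oncogenes and tumour suppressors, 0 passed limma's test at 12 h (9 at an unadjusted p under 0.05; 1 up and 7 down adjusted over the list alone; 5 down when paired). Their median was -0.088 (camera adjusted p = 0.0035; adjusted p = 0.226 with an estimated correlation). AMACR, a peroxisomal racemase raised in prostate tumours, was at -0.61 ± 0.15 (adjusted p = 0.072; paired fit, 0.0447), and the receptor kinase gene ERBB2 at -0.48 ± 0.11 (0.0581; paired fit, 0.0361). Of 20 genes repressed by MYC, 0 passed (4 at an unadjusted p under 0.05, 0 adjusted over the list alone, 2 when paired), with a median of -0.10 (camera adjusted p = 0.0151; adjusted p = 0.0515 with an estimated correlation). The tumour suppressor gene KLF6 in that list was at -0.47 ± 0.15 (adjusted p = 0.213; paired fit, 0.0408). The basal, stromal, endothelial and immune markers did not shift (7 tested, -0.13, camera adjusted p = 0.174). The 5 tested neuroendocrine markers had a median of -0.14 and did not pass camera (adjusted p = 0.135), while fry, which does not compare a list with other genes, gave them as lower (adjusted p = 0.0258). Of these, 1 was down adjusted over the list alone and in the paired fit, the synaptic vesicle gene SYT4 (-0.47 ± 0.12, adjusted p = 0.111; paired fit, 0.0328). Interferon response and antigen presentation (0.027, 0.729) did not shift, although TAP2, a peptide transporter, rose by 0.57 ± 0.12 (adjusted p = 0.0433). The 22 p53 target genes had a median of 0.040 and a camera direction of down (adjusted p = 0.968), with TP53INP1 at -0.60 ± 0.13 (adjusted p = 0.0552; paired fit, 0.0318).

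The cell cycle lists passed camera at 12 h only with its preset correlation, G1/S upward and G2/M downward. Of 32 genes of G1/S and DNA replication, 27 were higher, with a median of 0.19 (camera adjusted p = 3.6e-05; adjusted p = 0.327 with an estimated correlation). Singly 0 passed limma's test (6 at an unadjusted p under 0.05, 1 adjusted over the list alone, 4 when paired), with the checkpoint kinase gene CHEK1 at 0.58 ± 0.13 (adjusted p = 0.0581; paired fit, 0.0179). Of 31 genes of G2/M and mitosis, 24 were lower, with a median of -0.17 (camera adjusted p = 0.0141; adjusted p = 0.464 with an estimated correlation) and 0 passing limma's test (0 also at an unadjusted p under 0.05). The G2/M call was lost without vehicle 12 h replicate 1 (0.128) or 2 (0.31) and without Dox 12 h replicate 3 (0.441).

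At 5 h, 10 genes rose and 0 fell in the arrays labelled Dox. SOX8, a developmental transcription factor, rose most (1.35 ± 0.16, 2.55-fold, adjusted p = 0.0081), followed by STC2 (0.95 ± 0.12, adjusted p = 0.0082) and TWNK, the mitochondrial DNA helicase (0.92 ± 0.14, adjusted p = 0.03). The zinc finger gene ZNF239 rose by 0.87 ± 0.12, PPRC1, a coactivator of mitochondrial biogenesis, by 0.84 ± 0.13, and MNT by 0.84 ± 0.11 (adjusted p = 0.0133). GEMIN5 (0.83 ± 0.14), which assembles splicing particles, RAB3IL1 (0.83 ± 0.14), a Rab exchange factor, the glycolytic regulator gene PFKFB3 (0.75 ± 0.12) and the kinase gene PIM2 (0.63 ± 0.10) completed the set. By limma 771 genes had an unadjusted p under 0.05 (210 of them lower), with 568.2 to be expected by chance, and in 10.1% the groups did not overlap, against 10% by chance. The paired fit gave 48 rises and 3 falls, with all 10 calls kept. The count of 10 became 2, 3 and 5 without Dox 5 h replicate 1, 2 or 3, and 3 and 4 without vehicle 5 h replicate 2 or 3. It became 3, 6 and 5 without Dox 12 h replicate 1, 2 or 3, and 4 and 5 without vehicle 12 h replicate 1 or 3.

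Several of the same lists were also higher at 5 h. Of 43 MYC target genes, 40 were higher, with a median of 0.24 (camera adjusted p = 1.6e-13; adjusted p = 0.0677 with an estimated correlation), and PPRC1 alone passed singly (9 adjusted over the list alone, 3 when paired). Ribosome biogenesis had a median of 0.19 with 35 of 42 higher (camera adjusted p = 2.5e-12; adjusted p = 0.035 with an estimated correlation, 0.151 when paired). Of its members 0 passed limma's test (15 at an unadjusted p under 0.05, 11 adjusted over the list alone, 5 when paired), with TSR1 at 0.62 ± 0.12 (adjusted p = 0.0874; paired fit, 0.028). The ATF4 list rose by a median of 0.15 with 20 of 23 higher (camera adjusted p = 7.1e-06; adjusted p = 0.0163 with an estimated correlation, 0.151 when paired), STC2 alone passing singly (6 adjusted over the list alone). Glutamine use and amino acid transport rose by a median of 0.17 with 16 of 19 higher (camera adjusted p = 7.8e-05; adjusted p = 0.035 with an estimated correlation, 0.166 when paired). Of its members 0 passed (5 at an unadjusted p under 0.05, 2 adjusted over the list alone). Mitochondrial biogenesis and import rose by a median of 0.13 (camera adjusted p = 0.0006; adjusted p = 0.073 with an estimated correlation; 0 adjusted over the list alone, 4 at an unadjusted p under 0.05). With an estimated correlation, 3 lists held at 5 h, between 0 and 4 with 1 array left out, and 0 with median scaling or with only the 2 groups in the fit.

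Downward, 2 lists passed camera at 5 h. The median of 36 androgen receptor target genes was -0.069, with 25 lower (camera adjusted p = 0.0304; adjusted p = 0.073 with an estimated correlation), and that of 31 G2/M genes -0.15, with 27 lower (0.004; adjusted p = 0.481 with an estimated correlation). Singly 0 members of either passed limma's test (2 and 0 at an unadjusted p under 0.05, 0 adjusted over either list alone). Without vehicle 5 h replicate 1 both calls were lost (0.118 for the androgen receptor list and 0.212 for G2/M), as they were without Dox 5 h replicate 2 (0.0986 and 0.149). G2/M was lost also without Dox 5 h replicate 3 (0.096), and the androgen receptor list under the stricter detection filter (0.0702). The remaining lists did not pass at 5 h. Their camera adjusted p-values were 0.105 for serine and folate metabolism, 0.46 for purine salvage, 0.382 for pyrimidine synthesis, 0.0659 for RNA polymerase I and III, 0.323 for aminoacyl-tRNA synthetases and 0.256 for translation factors. For polyamine metabolism the value was 0.977, for the MYC network 0.0845, for genes repressed by MYC 0.0953 (0.0393 by fry), for luminal identity 0.261, for markers of other cell types 0.914 and for neuroendocrine markers 0.675. It was 0.407 for G1/S, 0.355 for p53 targets, 0.096 for oncogenes and tumour suppressors, 0.0845 for glycolysis, 0.891 for mitochondrial ribosomal proteins, 0.977 for the interferon list and 0.854 for cholesterol and fatty acid synthesis. Under other settings some passed camera. Glycolysis did so without background correction, with the authors' values, an offset of 50, no filter, the strict filter or array weights. It also passed without vehicle 5 h replicate 1 or Dox 5 h replicate 2. RNA polymerase I and III passed without a filter, with all probes, or without vehicle 5 h replicate 3 or Dox 5 h replicate 1. Serine metabolism, oncogenes and MYC-repressed genes passed only with an array left out.

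**Figure D4:**
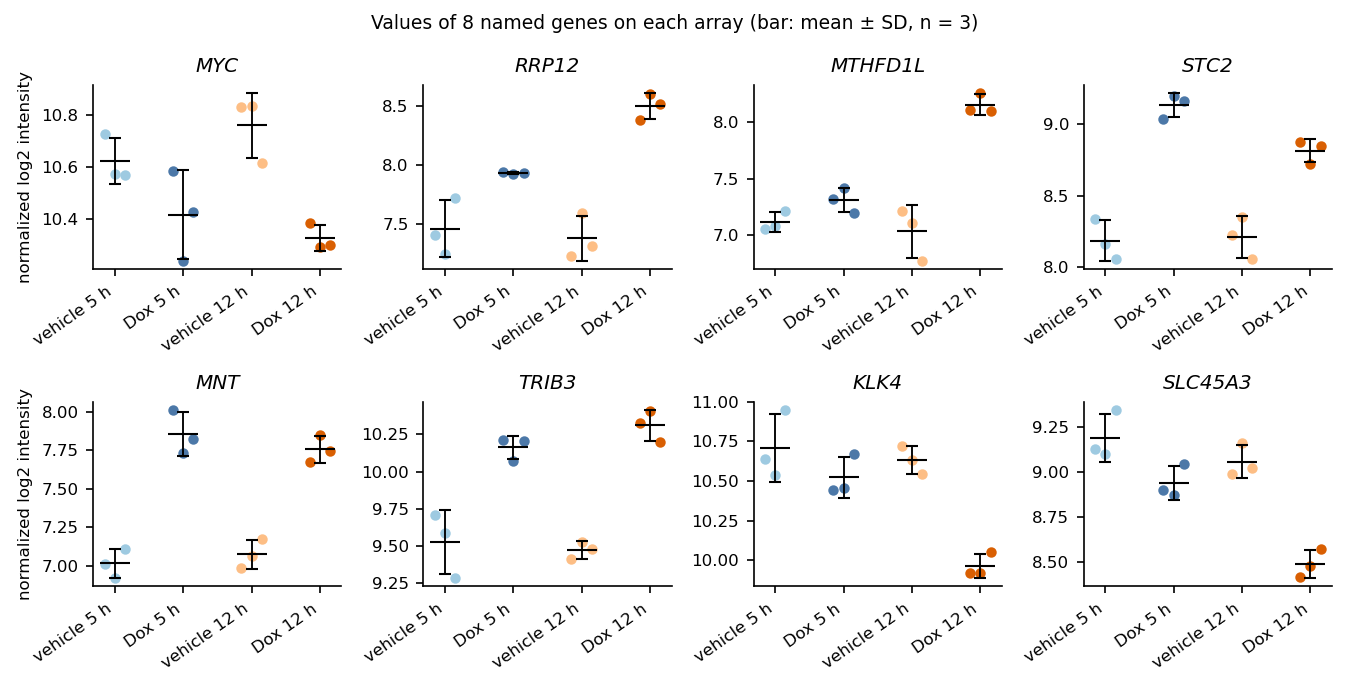
Normalized log2 intensity of 8 named genes on each array of the 4 groups (points), with mean ± SD (n = 3, bars). At 12 h the arrays labelled Dox all lay above the vehicle arrays for RRP12, MTHFD1L, STC2, MNT and TRIB3, and below them for MYC, KLK4 and SLC45A3.

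Most changes ran in the same direction at both times. Of the 10 genes that rose at 5 h, 7 also rose at 12 h, where independent lists would share 0.0906 (Fisher's exact test, one-sided, p = 4.8e-13; genes are not independent replicates). The paired fit shared 42, with 1.11 for independent lists. SOX8, PFKFB3 and PIM2 were called at 5 h but not at 12 h (adjusted p = 0.133, 0.0911 and 0.158), where the paired fit called SOX8 (0.045) and PFKFB3 (0.0244). The 103 genes that rose at 12 h had a median change of 0.68 at 12 h and 0.39 at 5 h, with 102 above 0 at 5 h, and all 13 genes that fell were lower at 5 h too. The overlap became 0, 1 and 2 without Dox 12 h replicate 1, 2 or 3, 1, 2 and 4 without Dox 5 h replicate 1, 2 or 3, 0 without vehicle 12 h replicate 1 or 3, and 2 and 4 without vehicle 5 h replicate 2 or 3.

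The difference between the effects at the 2 times was tested directly. For single genes it passed limma's test in 0 of 11364 cases (405 at an unadjusted p under 0.05; lowest adjusted p = 0.611), and in 0 with the paired fit. By camera, 8 lists were higher and 2 lower at 12 h than at 5 h relative to vehicle. All 10 were kept at the preset correlation when paired. With an estimated correlation 3 of these held, and none when paired (0.133 for each). They were aminoacyl-tRNA synthetases (median 0.23, 16 of 17 higher, adjusted p = 0.0193 with an estimated correlation), glutamine use and amino acid transport (0.21, 0.0413) and androgen receptor targets (-0.19, 26 of 36 lower, 0.0413). With 1 array left out, between 0 and 4 lists held with an estimated correlation, and 0 held with median scaling or a replicate block, but 7 held without background correction, with the authors' values, with an offset of 50 or without a detection filter.

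Without doxycycline, little separated the times. Vehicle arrays at 12 h against 5 h gave 0 changed genes by limma (416 at an unadjusted p under 0.05, with 568.2 to be expected by chance), groups without overlap in 6.99% of genes, against 10% by chance, and 0 of 27 lists. Cholesterol and fatty acid synthesis came closest among the lists, with a median of -0.11 (camera adjusted p = 0.0546). It passed as lower, and ribosome biogenesis as higher, without background correction, with the authors' values, an offset of 50, no detection filter, a replicate block or a trend and robust prior. Cholesterol synthesis alone passed with cyclic loess, the strict filter or array weights. Leaving out vehicle 12 h replicate 3 gave 3 lists, vehicle 5 h replicate 3 gave 2 and Dox 5 h replicate 2 gave 1, and with an estimated correlation 0 lists passed under any of these settings.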

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

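Of the tests in this part, those of exchanged labels, array scaling, the reach of the MYC probe, doxycycline without MYC and a rise in the vehicle arrays were chosen only after the result was seen.

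Lists whose Dox effect differed between the times are given as medians of the 12 h minus 5 h log2 difference, each past camera's adjusted test. Aminoacyl-tRNA synthetases differed by 0.23 and glutamine use and amino acid transport by 0.21, which held with an estimated correlation (adjusted p = 0.0193 and 0.0413) but not when paired (adjusted p = 0.133 for each). The ATF4 and endoplasmic reticulum stress list differed by 0.22 and serine and folate metabolism by 0.18 (adjusted p = 0.0565 and 0.0605 with an estimated correlation). MYC target genes differed by 0.15 and ribosome biogenesis by 0.14 (adjusted p = 0.206 for each with an estimated correlation). Mitochondrial ribosomal proteins differed by 0.090 (adjusted p = 0.0605 with an estimated correlation). G1/S and DNA replication differed by 0.20 (adjusted p = 0.49 with an estimated correlation); its call was lost without vehicle 5 h replicate 1 (0.0576), vehicle 12 h replicate 3 (0.116) or Dox 12 h replicate 2 (0.163). Luminal identity differed by -0.18 (adjusted p = 0.0605 with an estimated correlation), lost without vehicle 5 h replicate 1 (0.0905), and androgen receptor targets by -0.19 (adjusted p = 0.0413 with an estimated correlation, 0.133 when paired). Outside the named genes, 10 of 5548 unnamed probes were higher and 2 lower in the arrays labelled Dox at 12 h by limma's adjusted test (394 at an unadjusted p under 0.05), and 0 at 5 h (309 at an unadjusted p under 0.05).

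The first pattern is a MYC probe that lay lower while MYC target genes were higher in the arrays labelled Dox at 12 h. Exchanged labels would put the target genes lower in a line whose MYC transgene doxycycline induces, but their median was 0.40. That median is part of the pattern itself, and the MYC probes did not show the induction. It therefore cannot exclude exchanged labels. Scaling was argued against by the change closest to 0 over 4 other scalings, which was still -0.38. Whether the probe, at -0.43, reads the transcript of the construct cannot be told, since neither sequence was at hand; a probe reading only the cell's own MYC could give this pattern.

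The second pattern is the rise of the ATF4 list at 12 h. The 21 of 23 members held by no other list had a median of 0.36, 16 of them higher, so the rise did not rest on shared members. With so few members shared, leaving them out could hardly move the median. Whether the list rose apart from the other lists was not tested. Unfolded proteins in the endoplasmic reticulum were argued against by a set of 18 genes, made up of chaperones, degradation factors and XBP1. Their median was -0.092, with 4 higher and 0 called. The 4 were DNAJB9 (0.31), XBP1 (0.17), EDEM1 (0.097) and CANX (0.030), so the argument covers the set and not each gene. The bootstrap interval of the set's median, -0.192 to -0.030, resampled genes, not arrays. Camera gave the 18 genes p = 0.017 with its preset correlation and p = 0.191 with an estimated correlation. Of the 18, 7 are also in the ATF4 list. The 16 ATF4 list members outside this set had a median of 0.53. An action of doxycycline without MYC may also raise the list (0.38) and cannot be told apart, because no cells without the construct were measured.

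The third pattern is the lower level of androgen receptor targets at 12 h, by more than at 5 h. When paired, that difference passed camera with its preset correlation but not with an estimated correlation (adjusted p = 0.133). A rise in the vehicle arrays was argued against by their own change between the times, with a median of -0.029. Probe brightness was argued against because the list's median lay at percentile 0.010 of 10000 lists matched on mean value, the lowest of which was -0.14. Doxycycline acting without MYC could lower the list too (-0.19) and cannot be told apart, for want of cells without the construct.

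The 6 arrays of a time allow 10 splits, too few for a share under 0.05. For genes at 5 h the real split gave 10 and the highest other 52, so 2 of the 10 were as large. That other split set Dox replicates 1 and 3 with vehicle replicate 1 against the rest, which is the order of the arrays on the first principal component, and points to a structure of the samples. Among the 4 splits parting all 3 pairs the highest other count was 0, and with the paired fit the real split gave 51 and the highest other 0. For genes at 12 h the real split gave 103 rises and 13 falls and the highest other count was 0, with 1 of 10 as large. For the vehicle times the real count was 0, which all 10 splits reach by construction (highest other 0), so the splits decide nothing there. For lists the real split gave 8 at 5 h (highest other 3) and 19 at 12 h (highest other 9), with 1 of 10 as large in each. For the difference of the effects the real count was also 0, which all 100 splits within both times reach by construction (highest other 43), so they decide nothing either. For the overlap of 7 genes, 1 of 100 splits was as large, the real one itself (highest other 1). The other splits at 12 h called 0 genes, so hardly any could share as many, and the test does not decide whether chance gives such an overlap.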

How the results depend on the processing

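The replicate block within time points was chosen after seeing the data; the other alternatives were planned. The genes changed at 12 h (103 up, 13 down) became 395 with array weights, 228 with the authors' values, 225 without background correction, 197 with an offset of 50, 181 with the strict filter, 178 with a trend and robust prior, 373 with the block within time points and 0 with treat. Leaving out an array gave 9 to 139.

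The 10 genes at 5 h became 3 with array weights, 41 with the authors' values, 41 without background correction, 31 with an offset of 50, 35 with the strict filter, 35 with a trend and robust prior, 4 with median scaling, 0 with only the 2 groups compared, 51 with the block within time points and 0 with treat. Leaving out an array gave 2 to 12. The overlap of 7 became, in the same order, 3, 33, 32, 25, 27, 24, 2, 0, 42 and 0, and 0 to 7 without an array.

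Lists passing camera went from 19 to 10 at 12 h and from 8 to 3 at 5 h with an estimated correlation; leaving out an array gave 16 to 19 and 6 to 11. The calls with an estimated correlation depended on the setting: at 12 h they numbered 1 with median scaling, 5 with only the 2 groups compared, 7 with the replicate block, 9 with the block within time points and 10 to 13 with the other settings. At 5 h they numbered 0 with median scaling, only the 2 groups or the block within time points, 1 with array weights and 3 to 5 otherwise. Leaving out an array gave 9 to 11 and 0 to 4. Fry passed 15 lists at 12 h and 8 at 5 h (9 and 0 with median scaling). Treat gives no list result. For the genes, the overlap and the lists the cause was not tested. The difference of the effects and the vehicle times gave 0 genes by limma under every alternative run (405 and 416 at an unadjusted p under 0.05).

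No gene or list called above for Dox against vehicle at 5 h or 12 h reversed. Of the named called genes, 10 at 5 h and 48 at 12 h, 0 changed sign under the 27 alternatives. For CHAC1, NDP, POLR1G and SLC1A3 there were 26, since the strict filter removed them. All these genes lost the call under at least 1 alternative, 7 of the 48 only under treat. Lists and named genes not called above could change sign. With an array left out, lists did so in 17 cases at 5 h and 6 at 12 h (a list under a setting). Under other settings they did so in 18 and 6. For named genes the cases were 10 and 5 with an array left out, and 6 and 2 under other settings. The BeadChip as a block was not run, since no header gives the chip. Signal over background limits dim genes such as SLC1A3 and CHAC1, whose folds are bounds.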

Other observations

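The values below come from tables made for other comparisons, and their grouping was chosen only after the result was seen. The SD within a group, as the root of the mean variance over genes, was 0.238 for vehicle and 0.218 for Dox at 5 h, against 0.193 and 0.194 at 12 h (log2). The first 3 principal components held 22.9%, 19.7% and 13.3% of the variance. Within the ATF4 list, the chaperone gene HSPA5, chosen after its values were seen, was at -0.30 ± 0.14 at 12 h (limma adjusted p = 0.45).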
